A study of Mus musculus with 8 samples.

How the data were processed

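The data were 8 bulk RNA sequencing libraries of the mouse breast cancer lines 4T1 and TS/A, 2 per line and vector. Per the labels' protocols, total RNA was extracted with the RNeasy Mini Kit and libraries were made with the TruSeq RNA Library Preparation Kit v2, which does not mark strand, so reads of a gene and of an overlapping antisense gene could not be told apart. Groups were taken from the vector given in the sample characteristics, and line and replicate number from the titles. The titles contrast Emp_Control with Emp_ColIII where the characteristics contrast empty with Gpr56 vector, and the groups were kept as the characteristics give them.

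Each deposited file listed 65042 transcripts with a whole-number read count (the column of total gene reads) and an RPKM value, per the file headers. The aligner, counting program, genome build and annotation behind the authors' counts are not given in the sources used here. The deposited RPKM values equalled reads divided by transcript length and by 1 factor per library, within 0.001 in relative terms, for about 98% of transcripts with at least 21 reads (98.4% in 4T1 empty library 1). RPKM was used for that check and not in any test.

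The deposited counts were summed over transcripts to genes through GENCODE release M21 (GRCm38), in which 65023 of the 65042 transcript identifiers were found and 19 were not. This gave 22046 genes, 15828 with any read, 29 of which share a symbol with another gene. Coordinates are those of GENCODE M21. Depth ran from 10510569 to 25959142 reads per library, and 3 reads corresponded to 0.285 CPM in the shallowest library, 4T1 Gpr56 library 2. No pair of replicate libraries agreed within sampling noise: chi-square per degree of freedom was 3.68, 5.56, 123 and 18.1 in 4T1 empty, 4T1 Gpr56, TS/A empty and TS/A Gpr56, so no pair was merged as a repeated deposit of 1 library. This does not show that they came from separate cultures.

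Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (11982 genes), scaled by TMM and tested with glmQLFit and glmQLFTest in 1 fit of all 8 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05 without a fold limit. Contrasts were the vector effect in each line, their mean, their difference (TS/A minus 4T1) and TS/A against 4T1 with the empty vector. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. CPM of single genes are TMM-scaled, given as mean ± SD of 2 libraries, and summed levels of marker lists are plain CPM of the library total.

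Gene lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for 26 of 29 lists with at least 5 tested members. The lists held 680 members, of which 1 matched no gene. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The difference between vector effects, the lists, the single-line fit, the rule for named genes and the alternatives were fixed before the data were examined, except those said to be added. The list tests in the fit of 1 line alone were added.

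Named genes were Adgrg1 and, per line, the 8 largest increases and 8 largest decreases past the threshold with both libraries of a group on 1 side of both others, a mean of at least 10 CPM in the higher group and a standard symbol. For the difference between the lines the rule took the 4 smallest p values each way, and for lists up to 2 members each way past the threshold, or the most abundant members where none passed. Krt14 and Hspb1 in the difference between the lines, the list members taken from the fit of 4T1 alone and the genes near Adgrg1 fall outside that rule and were chosen after their values were seen. Some genes that the rule or the lists took are not reported here.

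The pipeline was tested on simulated data, with counts drawn from the means, library sizes and spread of the real libraries and 100 genes changed at each of 1.5-fold and 3-fold. With all 8 libraries and 4T1 changed, among 11966 genes, 0 of 100 genes changed 1.5-fold and 93 of 100 changed 3-fold were found, with 0 false among 93 calls. With 4T1 fitted alone, among 11371 genes, 86 and 100 were found, with 11 false among 197 calls. For TS/A, 16 and 96 were found with all 8 libraries, with 55 false among 167 calls in 11943 genes, and 2 and 89 were found with TS/A fitted alone, with 9 false among 100 calls in 11268 genes. Genes were drawn independently around 1 mean per line. The simulation thus held no shift shared by many genes of a library, such as that between the TS/A empty libraries. The biological coefficient of variation was 14.7% with all 8 libraries, 5.53% in 4T1 and 19.6% in TS/A.

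Alternatives were DESeq2 size factors in edgeR, library totals without TMM factors, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 10 CPM in 2 libraries, the fit of 1 line alone, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1 and an adjusted p under 0.01. Added after the data were seen were the same alternatives within each line alone, limma-voom with weights per cell line, and, for the epithelial list, a correction for length and GC content and thinning of reads to the smallest library. The median log2 fold change of all genes moved by less than 0.1 under every scaling. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.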

Results

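RNA sequencing covered 8 libraries from 4T1 and TS/A, 2 mouse breast cancer cell lines of BALB/c background. Per the sample characteristics, each line had been transduced with an empty virus vector or with a vector expressing Gpr56, now named Adgrg1, an adhesion G protein-coupled receptor that binds type III collagen. Each of the 4 groups held 2 libraries. RNA was taken after 72 h of culture, and the design text describes the transduced cells as grown with type III collagen in medium containing 10% FCS. The sample titles name the same groups differently, as Emp_Control against Emp_ColIII, so that the libraries given the Gpr56 vector in the characteristics also bear Emp in the title. By the labels alone, which vector and which collagen culture each group had is open, and every comparison of vectors carries that limit. Depth was 17903763 and 21625026 reads in 4T1 with the empty vector, and 21190814 and 10510569 reads in 4T1 with the Gpr56 vector. In TS/A it was 23121313 and 19598118 reads with the empty vector, and 25959142 and 21934048 reads in the libraries labelled with the Gpr56 vector. Nothing stated that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

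The first comparison asked whether the vector raised its own gene. Adgrg1 was far higher in 4T1 with the Gpr56 vector, at 95.3 ± 6.78 CPM (counts scaled to library size; SD, n = 2) against 2.65 ± 0.170 CPM with the empty vector. This was a 35.8-fold increase (log2 fold change 5.16, SE 0.43, adjusted p = 0.0086 by edgeR's quasi-likelihood test). Over 19 settings this log2 fold change ran from 5.09 to 5.23, and the call was lost in 4 of them. In TS/A, Adgrg1 stood at 17.96 ± 6.60 CPM in the libraries labelled with the Gpr56 vector and at 25.6 ± 13.1 CPM in those labelled with the empty vector (log2 fold change -0.51, SE 0.35, adjusted p = 1). The lines also differed with the empty vector, Adgrg1 in TS/A exceeding that in 4T1 by 3.27 on the log2 scale (SE 0.41, adjusted p = 4.41e-04). The 4T1 libraries empty 1, empty 2, Gpr56 1 and Gpr56 2 held 45, 59, 1934 and 1068 Adgrg1 reads. The same TS/A libraries held 849, 303, 594 and 288 reads. Adgrg1 (ENSMUSG00000031785) lies on chromosome 8 at 94974751 to 95014217 of GRCm38 in GENCODE release M21. The transduced gene parted the vector labels in 4T1 and not in TS/A, where the groups are named by their labels alone. Without TS/A empty library 1 the TS/A log2 fold change of Adgrg1 was 0.15, and without TS/A empty library 2 it was -0.95. Each of these rests on 1 empty library, so the spread of that group was not measured. They were the highest and lowest values over 19 settings.

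**Figure D1:**
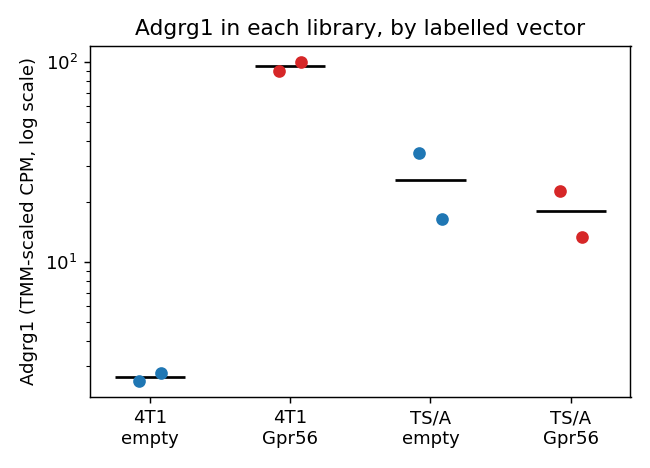
Adgrg1 level per library in CPM on a log axis, by cell line and vector label; points are libraries and bars are group means. The 4T1 libraries with the Gpr56 vector lie at 90.5 and 100.1 CPM, while the TS/A libraries of both labels lie between 13.3 and 34.8 CPM.

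In 4T1 with the Gpr56 vector, Cldn4, a tight junction claudin, rose from 109 ± 2.56 to 275 ± 13.7 CPM (n = 2 each; log2 fold change 1.34, SE 0.15, adjusted p = 0.031 in the fit of all 8 libraries). Mal, a proteolipid of apical membrane transport, rose from 49.9 ± 3.26 to 148 ± 10.2 CPM (1.56, SE 0.13, adjusted p = 0.0086). Hspb1, a small heat shock protein, rose from 3.41 ± 0.0345 to 17.1 ± 2.40 CPM (2.32, SE 0.20, adjusted p = 0.0086). Among the decreases, S100a4, a calcium-binding protein long linked to metastasis, fell from 472 ± 11.1 to 223 ± 4.32 CPM (-1.08, SE 0.14, adjusted p = 0.034). Col4a5, a type IV collagen chain, fell from 14.3 ± 0.899 to 2.53 ± 0.400 CPM (-2.53, SE 0.30, adjusted p = 0.031).

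Further increases in 4T1 included the annexin Anxa8 (1.27 on the log2 scale, 55.8 to 134 CPM) and Proser2 (1.25, 20.4 to 48.6 CPM). The prolactin relative Prl2a1, whose reads could be shared with other members of its family, also rose (1.53, 6.13 to 17.7 CPM). The 8 named decreases began with the adaptor Samsn1 (-3.29, 11.4 to 1.17 CPM). With S100a4 and Col4a5, the others were the actin-binding proteins Marcks (-2.44, 14.9 to 2.72 CPM) and Ppp1r9a (-2.31, 11.3 to 2.23 CPM), and the serine protease inhibitor Serpine2 (-2.14, 14.0 to 3.21 CPM). They also took in the lysophosphatidic acid receptor Lpar1 (-1.70, 10.2 to 3.12 CPM) and the leucine-rich proteoglycan Podnl1 (-1.37, 17.8 to 6.84 CPM). Their edgeR adjusted p values ran from 0.0086 for Mal to 0.048 for Serpine2. On GRCm38, Mal lies on chromosome 2 at 127633226 to 127656695, Hspb1 on chromosome 5 at 135887919 to 135889563 and Cldn4 on chromosome 5 at 134945119 to 134946934. The decreased S100a4 lies on chromosome 3 at 90603771 to 90606045 and Col4a5 on chromosome X at 141475385 to 141689234.

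In total, 15 genes rose and 12 fell in 4T1 among 11982 tested, with 1367 at an unadjusted p under 0.05, and all 27 also passed with the 4T1 libraries fitted alone. The count was 1267 without TS/A empty library 1 and 1252 without TS/A empty library 2, and 4 without either TS/A Gpr56 library. It was 0 without 4T1 empty library 1 or either 4T1 Gpr56 library and 1 without 4T1 empty library 2. The fit of all 8 libraries estimates the spread from both lines, so its 4T1 standard errors include the TS/A spread. With the 4T1 libraries fitted alone, 1300 genes rose and 1278 fell among 11373 (1612 and 1031 with library totals in place of TMM factors). The count of 2578 was 1583 without 4T1 empty library 1 and 1407 without 4T1 empty library 2.

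Epithelial adhesion and keratin genes moved upward in 4T1 (camera adjusted p = 4.82e-06 in the fit of all 8 libraries; adjusted p = 0.16 with an estimated correlation). With the 4T1 libraries fitted alone, 21 of 24 members rose, 1 fell and the median log2 fold change was 0.56. Rab25, a small GTPase of epithelial vesicle traffic, rose from 8.11 ± 0.631 to 23.5 ± 1.502 CPM (1.54, SE 0.13, adjusted p = 1.73e-06). The tight junction protein Tjp3 rose from 0.929 ± 0.118 to 3.19 ± 0.262 CPM (1.79, SE 0.35, adjusted p = 0.0020). Cldn3, also a tight junction claudin, fell from 15.3 ± 1.15 to 5.65 ± 0.900 CPM (-1.47, SE 0.16, adjusted p = 2.29e-05). Adjusted over the list alone, 21 members rose and 1 fell in that fit, and 13 rose and 1 fell in the fit of all 8 libraries. There Cldn4 was the member past the threshold over all genes tested. Taking members from the fit of 4T1 alone was decided after its counts were seen. Apart from Adgrg1, Cldn4, S100a4, Col4a5 and Serpine2 no member named by group passed with all 8 libraries.

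Basal and squamous genes moved upward too (adjusted p = 1.68e-04; adjusted p = 0.16 with an estimated correlation). In 4T1 alone 6 of 7 members rose, also adjusted over the list alone, with a median of 0.74. Krt16, a keratin of stressed epidermis, rose from 3.54 to 10.3 CPM (1.57, SE 0.20, adjusted p = 8.81e-05) and Sfn, an epithelial cell cycle inhibitor, from 106 to 179 CPM (0.76, SE 0.06, adjusted p = 6.20e-07). Mesenchymal and EMT genes moved downward (adjusted p = 0.0077; adjusted p = 0.64 with an estimated correlation). Of 12 members in 4T1 alone, 7 fell and 0 rose (8 fell adjusted over the list alone), among them S100a4. Twist1, a transcription factor of epithelial to mesenchymal transition, fell from 12.3 to 6.49 CPM (-0.90, SE 0.17, adjusted p = 0.0013). That list's call with all 8 libraries was lost without 4T1 empty library 2 (adjusted p = 0.057).

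**Figure D2:**
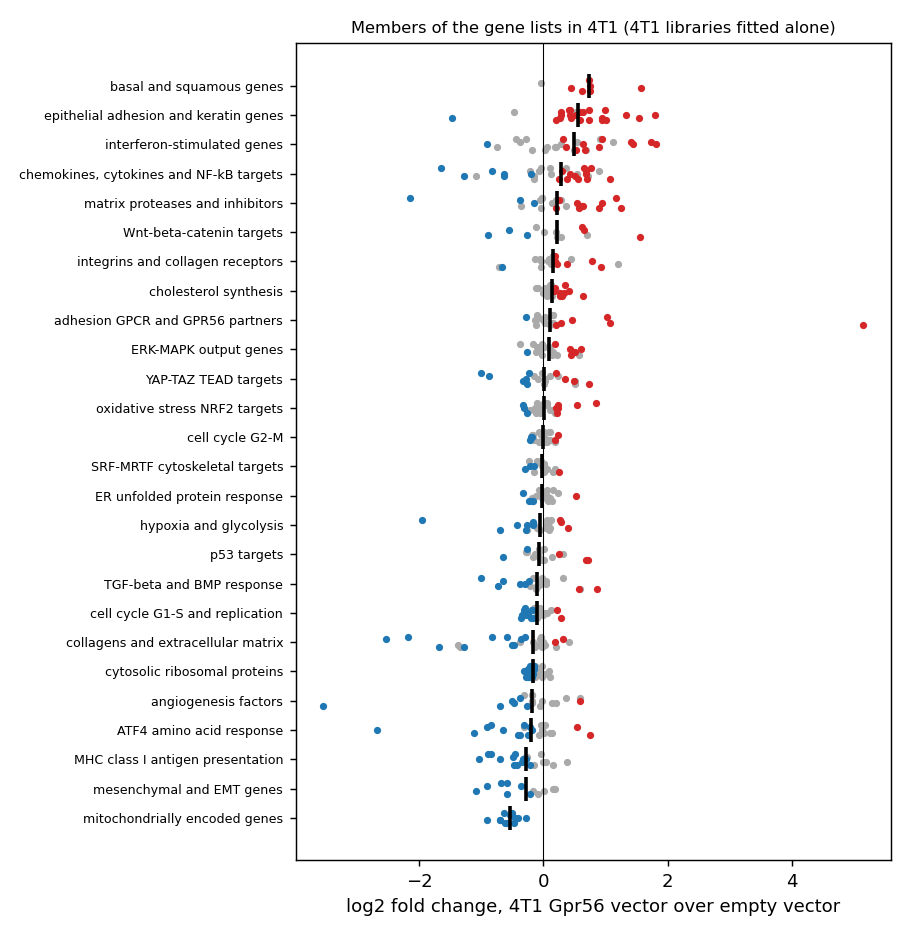
Log2 fold change in 4T1, Gpr56 vector over empty vector, for the members of 26 gene lists with the 4T1 libraries fitted alone; each point is a gene, red and blue points rose and fell at an adjusted p under 0.05, grey points did not pass, and black bars are list medians. The epithelial list shows 21 red points and 1 blue point, and the mitochondrially encoded list shows 13 blue points.

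Collagens and other matrix genes moved downward in 4T1 (adjusted p = 0.0012; adjusted p = 0.78 with an estimated correlation). In 4T1 alone 10 of 27 members fell and 2 rose (12 and 2 adjusted over the list alone). Col4a5 and the matrix protein Fbln1 fell (Fbln1 -2.18, SE 0.45, adjusted p = 0.0029) and the laminin chain Lama5 rose (0.31, SE 0.05). Matrix proteases and inhibitors moved upward (adjusted p = 9.51e-04; adjusted p = 0.38 with an estimated correlation). In 4T1 alone 10 of 24 members rose and 3 fell, or 13 and 3 adjusted over the list alone. Serpinb2, an inhibitor of plasminogen activators, rose from 44.6 ± 0.0899 to 105 ± 17.9 CPM (1.25, SE 0.09) and the collagenase Mmp13 from 3.85 to 8.67 CPM (1.17, SE 0.19). Serpine2 fell as given earlier. Integrins passed the set test only with 4T1 fitted alone (adjusted p = 0.049 against 0.26 with all 8 libraries; adjusted p = 0.39 with an estimated correlation; 6 of 19 members up and 1 down, also adjusted over the list alone). That call was lost without 4T1 empty library 2 (adjusted p = 0.14) and without 4T1 Gpr56 library 1 or 2 (adjusted p = 0.081 and 0.13). Itgb4, the laminin-binding integrin of hemidesmosomes, rose there from 49.7 ± 0.440 to 94.4 ± 2.67 CPM (0.92, SE 0.06, adjusted p = 3.37e-07).

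Interferon-stimulated genes moved upward in 4T1 (adjusted p = 1.98e-04; adjusted p = 0.74 with an estimated correlation). In 4T1 alone 11 of 27 members rose and 1 fell (13 and 1 adjusted over the list alone). The members with the largest increases were scarce, Cmpk2 at 0.859 to 2.97 CPM and Dhx58 at 0.564 to 1.90 CPM. Ifit2, an RNA-binding antiviral protein, fell from 21.1 to 11.2 CPM (-0.91, SE 0.13, adjusted p = 1.54e-04). MHC class I genes moved downward (adjusted p = 3.12e-04; adjusted p = 0.62 with an estimated correlation). In 4T1 alone 12 of 21 members fell and 0 rose, or 12 and 1 adjusted over the list alone. Nlrc5, the transactivator of MHC class I genes, fell from 12.6 ± 0.226 to 6.23 ± 0.470 CPM (-1.03, SE 0.16, adjusted p = 3.11e-04). H2-Q7, which has near-identical relatives that can share reads, fell by 0.89 on the log2 scale. The interferon call was lost without 4T1 Gpr56 library 1 (adjusted p = 0.091).

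Among metabolic groups, cholesterol synthesis genes moved upward in 4T1 (adjusted p = 0.014; adjusted p = 0.78 with an estimated correlation). In 4T1 alone 9 of 24 members rose and 0 fell (10 rose adjusted over the list alone). Fdft1, squalene synthase, rose from 118 ± 2.08 to 157 ± 7.33 CPM (0.41, SE 0.06, adjusted p = 2.04e-04). Genes of the ATF4 amino acid response moved downward (adjusted p = 0.037; adjusted p = 0.78 with an estimated correlation). In 4T1 alone 11 of 22 fell and 2 rose, also adjusted over the list alone. Chac1, a glutathione-degrading enzyme, fell from 21.3 to 9.70 CPM (-1.11, SE 0.13). With all 8 libraries, the cholesterol and ATF4 calls were both lost without 4T1 empty library 2 (adjusted p = 0.056 and 0.093) and without 4T1 Gpr56 library 1 (adjusted p = 0.053 and 0.11). All 13 mitochondrially encoded genes fell in 4T1 alone (13 adjusted over the list alone; median -0.53). Among them mt-Nd2 fell from 395 ± 85.8 to 241 ± 46.6 CPM and mt-Atp8 from 157 ± 44.8 to 82.6 ± 22.5 CPM. The set test for that list gave an adjusted p of 2.45e-05 (adjusted p = 0.62 with an estimated correlation). The mitochondrial share of reads was 0.755% and 0.965% with the empty vector and 0.652% and 0.568% with the Gpr56 vector. Ribosomal protein genes passed downward with 4T1 fitted alone (adjusted p = 1.33e-04; adjusted p = 0.39 with an estimated correlation; 20 of 31 members down, 24 adjusted over the list alone). So did G1-S cell cycle genes (adjusted p = 0.010; adjusted p = 0.30 with an estimated correlation; 11 of 25 down and 2 up, or 12 and 2 adjusted over the list alone). Neither list passed with all 8 libraries, but both did without either TS/A empty library, and the ribosomal list also without 4T1 empty library 1. With 4T1 alone the G1-S call was lost without 4T1 Gpr56 library 1 (adjusted p = 0.052).

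Summed markers of other cell types also differed between the 4T1 groups, but few members were expressed enough to be tested. The summed level of 20 immune cell markers was 7.65 and 7.77 CPM of the library total with the empty vector and 15.8 and 19.9 CPM with the Gpr56 vector. Cd68, a lysosomal glycoprotein abundant in macrophages, rose from 6.61 ± 0.0427 to 15.4 ± 2.80 CPM in 4T1 alone (1.20, SE 0.16, adjusted p = 1.30e-04). It made up most of the immune sum, and was the 1 of 2 tested immune markers to pass. The sum of 13 fibroblast markers was 16.3 and 16.0 CPM against 9.30 and 10.5 CPM, and 1 of 3 tested fell in 4T1 alone. The 12 endothelial markers summed to 13.1 and 12.1 CPM against 14.1 and 16.7 CPM, and 0 of 3 tested passed in 4T1 alone. Over 26 lists tested in 4T1, 5 moved upward and 5 downward by camera, 0 passed with an estimated correlation (lowest adjusted p = 0.16). By fry 1 list passed, the basal one (adjusted p = 0.023). With 4T1 fitted alone, 13 lists passed by camera, 13 by fry and 0 with an estimated correlation. In the lists past the threshold, median, mean and test had the same sign. With all 8 libraries the other 16 lists had camera adjusted p values from 0.052, for G1-S genes and for ribosomal proteins, to 0.836, for p53 targets. The list of adhesion receptors and GPR56 partners, whose member past the threshold was Adgrg1, had an adjusted p of 0.076.

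In TS/A, the libraries labelled with the Gpr56 vector had lower mitochondrially encoded genes and higher genes of the ATF4 amino acid response. Across all 11982 tested genes, however, the 2 TS/A groups did not overlap for 21.7%, against 59.8% in 4T1. A random division of 4 libraries into 2 and 2 gives 33.3%, so the TS/A labels parted fewer genes than that. The mitochondrial list had a median log2 fold change of -0.63 (camera adjusted p = 8.26e-11; adjusted p = 0.45 with an estimated correlation). Its most abundant members were mt-Co3, at 1509 ± 137 against 2046 ± 271 CPM, and mt-Co1, at 990.4 ± 69.7 against 1329.9 ± 558 CPM (n = 2 each; edgeR adjusted p = 1 for both). For mt-Co1 the groups overlapped, as empty library 2 stood at 935 CPM, below both Gpr56 libraries (1039.7 and 941 CPM). The ATF4 list had a median of 0.48 (adjusted p = 8.26e-11; adjusted p = 0.45 with an estimated correlation), less than the 0.69 between the 2 empty-vector libraries. Without TS/A empty library 1 its adjusted p was 0.036. Phgdh, the first enzyme of serine synthesis, stood at 1112 ± 125 against 937 ± 434 CPM and Atf4 itself at 802 ± 96.6 against 614 ± 168 CPM. For Phgdh empty library 2 lay above both Gpr56 libraries (1243 against 1024 and 1199.9 CPM), and for Atf4 it stood level with the lower of them (733 and 734 CPM). No member of either list passed over all genes tested. Adjusted over the list alone, 5 of 13 mitochondrial genes fell (1 of 13 with TS/A fitted alone) and 0 of 23 ATF4 genes passed. The mitochondrial share of reads was 0.859% and 0.655% with the empty vector and 0.517% in both libraries labelled with the Gpr56 vector.

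Smaller shifts were found for ribosomal proteins (median 0.14, adjusted p = 0.0011; adjusted p = 0.91 with an estimated correlation) and hypoxia genes (0.12, adjusted p = 0.014; adjusted p = 0.58 with an estimated correlation), both upward. Cholesterol synthesis (-0.14, adjusted p = 0.0051; adjusted p = 0.84 with an estimated correlation) and G1-S genes (-0.09, adjusted p = 0.0073; adjusted p = 0.64 with an estimated correlation) moved downward. No member of these 4 lists passed over all genes tested or adjusted over the list alone. By camera 6 of 26 lists passed, against 0 by fry and 0 with an estimated correlation. The count was 10 without TS/A empty library 2 or TS/A Gpr56 library 1 and 3 without TS/A Gpr56 library 2. None of these 4 calls held for every TS/A library left out. The ribosomal list turned downward without TS/A empty library 1 (adjusted p = 5.60e-05) and was lost without TS/A Gpr56 library 2 (adjusted p = 0.18). The hypoxia call was lost without the same 2 libraries (adjusted p = 0.89 and 0.27) and with TS/A fitted alone (adjusted p = 0.071), where chemokine genes passed downward instead (adjusted p = 0.031; adjusted p = 0.91 with an estimated correlation). That call was lost without any single TS/A library (adjusted p from 0.055 to 0.41). The G1-S call was lost without TS/A empty library 2 (adjusted p = 0.60) and without TS/A Gpr56 library 2 (adjusted p = 0.63). Cholesterol synthesis was not called without either empty library (adjusted p = 0.22 and 0.075) or without TS/A Gpr56 library 2, where it turned upward (adjusted p = 0.79).

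Prl2c2, proliferin, was the single gene past the threshold in TS/A, falling from 164 ± 8.56 to 62.3 ± 5.21 CPM (-1.40, SE 0.12, adjusted p = 0.033 by edgeR with all 8 libraries; 415 genes at an unadjusted p under 0.05). It lies on chromosome 13 at 12996125 to 13005383, and its near-identical copies Prl2c3 and Prl2c5 can share its reads, so its level is uncertain. With the TS/A libraries fitted alone 0 of 11289 genes passed in edgeR (114 at an unadjusted p under 0.05), against 3 in DESeq2, 0 in limma-voom and 26 in edgeR with the replicate number as a block. In data simulated with the spread of TS/A the fit of all 8 libraries made 55 false calls among 167, though without shifts shared by many genes of a library.

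The 2 TS/A empty-vector libraries differed from each other more than any other pair, with 877 of 11982 genes over 1 log2 apart against 297 to 388 in the other groups. Collagen and matrix genes were higher in library 1 by a median of 0.81 (28 of 29 members). Its ribosomal protein genes differed by a median of -0.86 (0 of 31 higher) and its ATF4 genes by a median of -0.69 (2 of 22 higher). Between TS/A Gpr56 libraries 1 and 2 these lists differed in the same directions by less. The medians there were 0.25 for collagen and matrix genes, -0.19 for ribosomal proteins and -0.40 for ATF4 genes. These shifts thus followed the replicate number under both labels. The 13 fibroblast markers summed to 355 CPM of the library total in TS/A empty library 1, 141 CPM in empty library 2, and 219 and 158 CPM in the Gpr56 libraries. Col1a1, with 7591 and 2572 reads in empty libraries 1 and 2, made up most of the sum in both. Leaving out a library leaves 1 in its group, which then adds nothing to the estimated spread. The counts that follow show how far the calls depend on that library and are not reliable calls. Without TS/A empty library 1, 51 genes rose and 167 fell in TS/A. Without library 2, 1370 rose and 1543 fell, and without any other single library the count was 0. Of 106 genes called in both settings, 20 had the same sign and 86 opposite signs.

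**Figure D3:**
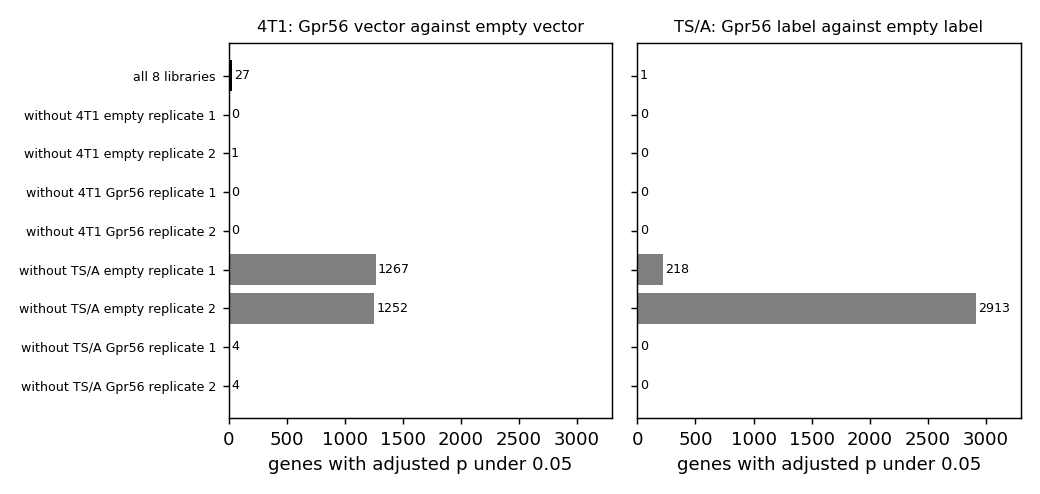
Number of genes past an adjusted p of 0.05 with all 8 libraries and with each library left out in turn, for the vector comparison in 4T1 and in TS/A. A library left out leaves 1 in its group, which then adds nothing to the estimated spread. The count in TS/A is 218 without empty library 1 and 2913 without empty library 2, against 1 with all 8 libraries.

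Of the 2578 genes called with 4T1 alone, 50.8% had the same sign in TS/A. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.0022 and a Spearman rho of 0.03. No gene passed in both lines with all 8 libraries, for which the 1 gene in TS/A left little room (0.0010 shared genes expected by chance). For the mean of the 2 within-line differences, 7 of 26 lists passed by camera, 0 with an estimated correlation and 0 by fry. Among them the mitochondrial list moved downward (camera adjusted p = 1.40e-10; adjusted p = 0.55 with an estimated correlation). That list did not differ between the lines by camera (adjusted p = 0.67). For the same mean, 0 of 11982 genes passed in edgeR's quasi-likelihood test (1001 at an unadjusted p under 0.05), against 71 in DESeq2, 0 in limma-voom and 17 in edgeR with the replicate number as a block. Without TS/A empty library 1 the count was 1179, and without library 2 it was 1905.

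A direct test of the difference between the lines found 8 genes, 2 with a higher and 6 with a lower difference in TS/A than in 4T1 (767 at an unadjusted p under 0.05). Mal rose in 4T1 by 1.56 and stood at -1.44 in TS/A (difference -3.01, SE 0.23, adjusted p = 0.0079). Vcam1, an adhesion molecule for leukocytes, fell in 4T1 by 0.89 and stood at 0.71 in TS/A (difference 1.60, SE 0.18, adjusted p = 0.035). Adgrg1 differed by -5.67 (adjusted p = 0.021) and Anxa8 by -1.76 (adjusted p = 0.033). Prl2c2 differed by -2.38 (adjusted p = 0.0079) and Epdr1, an ependymin relative, by 4.11 (adjusted p = 0.039). The count was 294 without TS/A empty library 1, 2379 without TS/A empty library 2, 1 without 4T1 empty library 2 and 0 without any other library. By camera 11 of 26 lists differed between the lines, and 0 with an estimated correlation (lowest adjusted p = 0.22). Among the 11, the epithelial list had the lower response in TS/A (adjusted p = 2.68e-05) and the ATF4 list the higher (adjusted p = 6.27e-08). Of the 24 epithelial members tested here, 12 had enough reads to be tested with TS/A fitted alone. Krt8, for example, stood at 0.449 CPM in TS/A with the empty vector. For such scarce members a lower response cannot be told from too few reads.

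With the empty vector, TS/A had far less of most epithelial genes than 4T1 and more of most mesenchymal ones. Of 24 epithelial members 23 were lower in TS/A and 0 higher, also adjusted over the list alone (camera adjusted p = 9.70e-12; adjusted p = 0.098 with an estimated correlation). Cdh1, E-cadherin, stood at 275 ± 11.2 CPM in 4T1 and 0.082 ± 0.12 CPM in TS/A, Krt8 at 738 and 0.449 CPM and Krt7 at 548 and 0.232 CPM (n = 2 each). Mesenchymal genes were higher in TS/A for 12 of 19 members and lower for 3, or 12 and 4 adjusted over the list alone (adjusted p = 0.041; adjusted p = 0.68 with an estimated correlation). Summed fibroblast markers were higher beside them, at 355 and 141 CPM of the library total against 16.3 and 16.0 CPM in 4T1. Most of the TS/A sum was Col1a1, at 225 ± 122 CPM. Of 4 fibroblast markers tested, 2 were higher and 0 lower past the threshold, with a lowest log2 fold change of -1.08. Whether TS/A cells or others carried these markers was not tested. N-cadherin, Cdh2, stood at 0.047 CPM in 4T1 and 109 CPM in TS/A. The homeobox gene Prrx1 stood at 81.5 CPM in TS/A with no read in 4T1, which allows up to 0.168 and 0.139 CPM in its empty-vector libraries.

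Oxidative stress genes of the NRF2 program were also higher in TS/A (13 of 23 up and 2 down, also adjusted over the list alone; adjusted p = 0.0048; adjusted p = 0.16 with an estimated correlation). The quinone reductase Nqo1 stood at 44.8 CPM in 4T1 and 315 CPM in TS/A (2.82, SE 0.12, adjusted p = 1.18e-06). Chemokine and cytokine genes were lower (4 up and 13 down of 30, also adjusted over the list alone; adjusted p = 0.041; adjusted p = 0.45 with an estimated correlation). The cytokine Il1a stood at 207 CPM in 4T1 and 0.17 CPM in TS/A. Basal genes (5 of 7 down, also adjusted over the list alone; adjusted p = 0.0012; adjusted p = 0.16 with an estimated correlation) were lower in TS/A. So were matrix proteases (15 of 28 down and 6 up, also adjusted over the list alone; adjusted p = 0.041; adjusted p = 0.58 with an estimated correlation). G2-M genes (12 of 25 down and 3 up, or 14 and 3 adjusted over the list alone; adjusted p = 0.043; adjusted p = 0.67 with an estimated correlation) were lower as well. Cholesterol synthesis genes were higher (12 of 25 up and 2 down, or 13 and 2 adjusted over the list alone; adjusted p = 0.040; adjusted p = 0.88 with an estimated correlation). Across all genes 2859 were higher and 2814 lower in TS/A, and the count of 5673 was 3341 without 4T1 empty library 1 and 3351 without 4T1 empty library 2. The first principal component of all 8 libraries parted the lines and held 88.5% of the variance.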

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

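The test of the difference between the lines was planned, whereas the tests that weigh the Adgrg1 result in TS/A were chosen after it was seen. A difference between the 2 lines in their response to the vector label brought out 8 genes, by edgeR's interaction test on all 8 libraries. Adgrg1 itself differed by -5.67 (adjusted p = 0.021), at 5.16 in 4T1 and -0.51 in TS/A on the log2 scale. Mal, a proteolipid of apical transport, differed by -3.01 (adjusted p = 0.0079), higher in both 4T1 Gpr56 libraries and lower in both TS/A Gpr56 libraries than in their empty-vector libraries. Its level in TS/A was low, at 3.16 and 3.02 CPM with the empty vector and 0.990 and 1.29 CPM with the Gpr56 label. Prl2c2, proliferin, differed by -2.38 (adjusted p = 0.0079), at 0.98 in 4T1 and -1.40 in TS/A, with reads that can be shared with its copies. Hspb1, the small heat shock protein, differed by -2.37 (adjusted p = 0.037), at 2.32 in 4T1 and -0.04 in TS/A. The basal keratin Krt14 differed by -1.95 (adjusted p = 0.037), at 0.62 and -1.32, and Anxa8 by -1.76 (adjusted p = 0.033), at 1.27 and -0.50. In the other direction, Vcam1 differed by 1.60 (adjusted p = 0.035), at -0.89 and 0.71, and Epdr1 by 4.11 (adjusted p = 0.039), at -4.02 in 4T1, where it had 66, 74, 7 and 0 reads, and 0.09 in TS/A, where it had 1558 to 2280 reads. Each gene passed in 8 to 11 of 18 settings, and the highest adjusted p over them was 0.53, for Krt14. Without TS/A empty library 1 the interaction called 294 genes, without TS/A empty library 2 it called 2379, without 4T1 empty library 2 it called 1, and without any other library 0.

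For Adgrg1, which was not higher in the TS/A libraries labelled with the Gpr56 vector, a transgene as abundant as in 4T1 is argued against. The higher Gpr56 library reached 22.6 CPM, where the empty-vector mean plus the 4T1 increase comes to 118 CPM. That shortfall is beyond the 21.5 CPM range of the 4 libraries. For a swap between the 2 TS/A groups, the widest parting of Adgrg1 by any division of those libraries into 2 and 2 was 1.39-fold. This argues against a swap of libraries with so abundant a transgene. It cannot decide on a swap with a weaker one, which would leave the same overlap. For a 4T1 library under a TS/A label a first test came out on the side of the explanation, with epithelial genes 5.33 times higher in the lowest 4T1 library than in the highest TS/A library where more than 10 times had been set, as TS/A carries some of that list in all its libraries (535 to 584 TMM-scaled CPM). A second test, added after that outcome, argues against it, because the lowest correlation over all tested genes between 2 TS/A libraries, 0.979, exceeded the highest between a TS/A and a 4T1 library, 0.840, by 0.139. It stays open that the TS/A arms may differ in collagen rather than in the vector, as the titles read. For Adgrg1, 0 of the TS/A Gpr56 libraries lay above both empty-vector libraries, and no library carries only 1 of these factors. The 4T1 titles read the same way, yet Adgrg1 differed 35.8-fold between the 4T1 arms. In 4T1 the titles thus leave out a vector difference, so they cannot be relied on alone for TS/A. A vector that was lost or silenced, or a weak increase hidden by the spread of the empty-vector libraries, was not tested.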

How the results depend on the processing

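The alternatives were planned, except weights per cell line, the list tests with 1 line fitted alone and the settings within each line fitted alone. These were chosen after the data were seen. Of the values for single named genes, 279 of 449 kept their direction and their side of the threshold, 168 kept direction and lost the call, 1 gained it and 1 reversed. Adgrg1 in TS/A reversed to 0.15 without TS/A empty library 1 and ran down to -0.95 without TS/A empty library 2. In both settings 1 empty library remained, so the spread of that group was not measured. Calls were lost mainly when a 4T1 library was left out (23 of 24 each) or a TS/A Gpr56 library (20 of 24 each). The fit of all 8 libraries estimated the spread of each gene from both lines. Its biological coefficient of variation was 14.7%, against 5.53% in 4T1 alone and 19.6% in TS/A alone. The 4T1 standard errors of that fit thus include the TS/A spread, so leaving out a TS/A library can move the 4T1 calls. Other causes of these changes were not tested.

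For 4T1, TS/A, the mean of both and the difference between the lines, the counts with all 8 libraries were 27, 1, 0 and 8 genes. DESeq2 gave 266, 10, 71 and 66, and no filter gave 253, 8, 62 and 58. Library totals gave 0 in TS/A (edgeR) and 4 for the difference. Limma-voom gave 57 in 4T1 and 0 for the difference, and limma-voom with weights per cell line gave 1753 in 4T1, 1 for the mean and 2 for the difference. With each line fitted alone, edgeR called 2578 in 4T1 and 0 in TS/A. At an adjusted p under 0.01 edgeR gave 3 in 4T1, 0 in TS/A and 2 for the difference. Leaving out a library gave 0 to 1267 in 4T1, 0 to 2913 in TS/A, 0 to 1905 for the mean and 0 to 2379 for the difference, with the high values without TS/A empty library 1 or 2. The baseline of the lines, 5673, became 2716 with a log2 fold change of at least 1, 3625 at an adjusted p under 0.01, and 3341 to 7853 with a library left out. A fit of 1 line has no value for the last 3 contrasts, and the pseudocounts listed for normalized values were not run since the values are counts.

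The replicate number as a block gave 130 genes in 4T1 (77 up, 53 down), 17 for the mean, 37 for the difference and 26 with TS/A alone (20 up, 6 down), 11 lists in 4T1 and 8 in TS/A, and moved no other count by over 1.5 times. Across genes, deviations from the group mean in same-numbered libraries correlated at -0.02 in 4T1 and 0.31 in TS/A. The first principal component of the TS/A libraries (57.7% of the variance) put replicates 1 at -37.8 and -4.66 and replicates 2 at 25.8 and 16.6. The numbers were not taken to pair the samples. In TS/A a difference shared by same-numbered libraries is not excluded, and it was not weighed as a cause of the spread.

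With 4T1 alone, 2578 genes became 1535 in DESeq2, 275 with a log2 fold change of at least 1, 1347 at an adjusted p under 0.01, and 1407 (without 4T1 empty library 2) to 2695 with a library left out. With TS/A alone, 0 genes in edgeR (114 at an unadjusted p under 0.05) became 3 in DESeq2, 4 with no filter, and 4 to 1007 with a library left out (1007 without TS/A empty library 2). Of 10 lists called in 4T1, 0 passed with an estimated correlation and 1 by fry, and 7 to 12 with a library left out. With 4T1 alone 13 passed by camera and 13 by fry, not all of them the same lists. Of 6 in TS/A, 0 passed with an estimated correlation, 0 by fry, and 3 to 10 with a library left out. The correlation between the lines, 0.0022, ran from -0.0302 without TS/A Gpr56 library 2 to 0.0388 without TS/A Gpr56 library 1. Low read counts limit genes such as Cmpk2 and Tjp3 in 4T1, mainly with the empty vector, where both were scarce.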

Other observations

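The members of further groups named here come from the planned fit of the 4T1 libraries alone but were picked after its counts were seen, and of the tests weighed here those on growth state and on a mixture of subclones were chosen after the result was seen. For the epithelial list, the correction for length and GC content and the thinning were also added after the data were seen. In 4T1 with the Gpr56 vector, genes of the Wnt group moved in both directions (3 of 12 up and 3 down, also adjusted over the list alone; camera adjusted p = 0.41). Wnt10a, a secreted Wnt ligand, rose from 5.73 ± 0.330 to 16.9 ± 0.678 CPM (1.55, SE 0.15, adjusted p = 5.66e-06) and Wnt7a from 53.3 to 83.8 CPM (0.65, SE 0.06), while the Wnt receptor Fzd7 fell from 19.8 to 10.7 CPM (-0.90, SE 0.13). Chemokine and cytokine genes also split, with 12 of 30 up and 6 down, or 13 and 6 adjusted over the list alone (adjusted p = 0.16). Ccl20, a chemokine for CCR6-bearing cells, rose from 8.16 to 17.2 CPM (1.07, SE 0.16), and Icam1, a leukocyte adhesion molecule, fell from 10.98 to 4.52 CPM (-1.28, SE 0.17, adjusted p = 1.29e-04). Of 18 angiogenesis factors 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.12), and Vegfa, the main endothelial growth factor, fell from 25.6 ± 2.66 to 15.6 ± 1.58 CPM (-0.70, SE 0.12, adjusted p = 9.43e-04).

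Adgrg3, a receptor gene that follows Adgrg1 on chromosome 8 (95017692 to 95045250), rose in 4T1 alone from 8.81 ± 0.358 to 18.5 ± 0.844 CPM (1.08, SE 0.13, adjusted p = 5.37e-05), with an adjusted p of 0.092 in the fit of all 8 libraries. In TS/A its log2 fold change was 0.07. Against TS/A empty library 2 and empty library 1 in turn, Mal (-1.41 and -1.475 on the log2 scale) and Krt14 (-1.23 and -1.39) were lower in the libraries labelled with the Gpr56 vector. So were the mitochondrial genes mt-Atp6 (-0.62 and -0.57) and mt-Nd3 (-1.32 and -0.62), while Hmox1, heme oxygenase, was higher (0.58 and 0.45). These genes were picked after their values were seen. Both comparisons use the same 2 Gpr56 libraries against 1 empty library, so agreement is partly built in. Across all genes 39.3% had the same sign in both.

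Epithelial genes were higher in 4T1 with the Gpr56 vector, by a median of 0.56 on the log2 scale with 4T1 fitted alone. Length and GC content are argued against, as the median after a spline correction per library was 0.55, with 20 members up and 1 down. Unequal depth is argued against as well, since 21 members still passed upward after thinning to the smallest library. A different mixture of epithelial and mesenchymal subclones in the separately transduced cultures may account for the pattern and stays open, because the mesenchymal list moved the other way (median -0.29) and the labels do not say whether the libraries of an arm came from separate transductions. An effect of the vector or of collagen is open too, and the design does not part them from each other. Adgrg1 showed a vector difference between the 4T1 arms (2.65 against 95.3 CPM), whereas a collagen difference between them rests on the titles alone.

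The 2 TS/A empty-vector libraries stood apart from each other, with a biological coefficient of variation of 19.6% in TS/A against 5.53% in 4T1. A few dominant genes are argued against, since it was 19.5% without the 100 genes with the most reads. Deviations followed transcript length with opposite sign in the 2 libraries (correlation across genes 0.49 and -0.44). Correcting length and GC content brought the coefficient to 14.5%, against 5.17% in 4T1 after the same correction. Such a bias could be part of the spread, but as corrected here it did not bring TS/A to the level of 4T1. The value lies between the bounds of 10% and 15% set beforehand, so the test does not decide on the bias as the whole cause. After that correction edgeR still called 0 of 11287 genes in TS/A (207 at an unadjusted p under 0.05). A different growth state also stays open, as the G1-S and G2-M lists differed between the 2 libraries by medians of -0.125 and 0.07, neither beyond 0.5 nor both near 0.

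For the mean of both lines, the 18 splits that keep 2 libraries of each line on each side are too few for a share under 0.05. The real split gave 0 genes in edgeR (1001 at an unadjusted p under 0.05), so all 18 splits gave at least as many whatever their labels, and the highest other gave 320. That split and one with 89 genes part 4T1 as labelled and TS/A replicate 1 from replicate 2.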
